A study of Mus musculus with 4 samples.

How the data were processed

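RNA immunoprecipitation followed by sequencing (RIP-seq) was recorded for livers of male C57BL/6 mice given an adeno-associated virus (AAV) that carries either GFP, the control, or NAT10. For each virus the labels list 1 immunoprecipitated (IP) library and 1 input library, 4 libraries in all, with no replicate of any kind. The labels' protocols describe an antibody against a protein of interest, with an IgG option, ribosomal RNA removal and paired-end sequencing, and they also carry a library type naming ac4C (N4-acetylcytidine). Whether the antibody bound NAT10 or ac4C is therefore not settled by the labels. The same protocols name db/db and lean mice as the RNA source, which the sample titles do not.

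The deposited data were 2 peak lists, 1 per virus, each holding peaks of the IP library against its input. The peaks carry MACS names, per the file headers; the MACS version, the aligner and the read filters are not given in the sources used here. The genome build is mm10, per the submitters' processing notes. The fold enrichment of each peak is a linear ratio over background that the authors' peak caller gave, per the file headers. The peak score deposited by the authors is -10 times log10 of the peak's p-value. It was at least 50 in both lists. It was held at 3100 or slightly above for the peaks with the smallest p-values, so that scores at this ceiling have no order. The FDR column was read as a percent, as deposited by the authors. It was between 0 and 18.18 in the AAV-GFP list and between 2.44 and 40 in the AAV-NAT10 list. The FDR did not fall steadily as the score rose. In AAV-GFP the Acsl1 peak at score 3100 had an FDR of 11.07, and an Abca1 peak at 392.33 had 4.57. In AAV-NAT10 the Igf1 peak at 3100 had 4.58, and an Abca1 peak at 408.82 had 2.6. A score at the ceiling therefore does not mark the lowest FDR. All other columns used (positions, lengths and gene names) are those of the deposited lists. Folds and scores are the authors' values for single peaks and were used only to describe, rank or filter peaks within a list. Values of both lists set side by side do not measure a change.

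Starts in the lists count from 0. Of the AAV-GFP peaks, 1251 began exactly at the start of their gene in RefSeq (GRCm38.p6, the assembly of mm10) once 1 was added, and 1269 ended at its end; positions are given counted from 1. Gene names are those of the lists. RefSeq held 7026 of the 7462 names in the AAV-GFP list and 8009 of the 8508 in the AAV-NAT10 list. The lists give no strand, so overlapping genes cannot be told apart. The peaks appear cut to annotated exons, since 25001 peaks had the same 2 borders in both lists; a fold or score can then belong to a wider peak than the piece listed. No peak of a list touched another of the same list.

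Peaks were counted as overlapping where they shared at least 1 base. A gene had a peak where a list assigned it at least 1. The covered length of a gene is the sum of its peak lengths. Since the peaks appear cut to exons, it also depends on exon length. Because each group is 1 library, no test between the viruses was made and no p-value is given; shares of peaks or genes have exact (Clopper-Pearson) 95% intervals that cover counting error only. Read counts and library depths are unknown here, and differences in depth or IP yield between the libraries enter every count of peaks. A gene without a listed peak may still have been bound.

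Before the data were examined, 19 gene lists with 338 members, the processing alternatives and a rule for the genes to name were fixed. The rule took Nat10, the 10 genes with the highest peak fold in each list, the 10 genes with the largest covered length among those with a peak in only 1 list (for each virus), and in each gene list up to 2 members with the largest covered length difference toward each virus; predicted genes were passed over, and 1 gene that the rule selected is not reported here. For each gene list with at least 3 members holding a peak, the median difference in covered length (AAV-NAT10 minus AAV-GFP) was set against 10000 random gene lists of the same size, matched on mean covered length in 10 classes. The percentile describes these libraries and is not a p-value. In 200 simulated unchanged lists of 15 genes, 2.0% were placed in the highest 2.5% of random lists; with 300 bases added to every member, 36.0% were, so moderate shifts of a small list would often be missed. Chosen after the data were seen were the share of overlapped peaks by score, the share of members with a peak only in AAV-NAT10, the share of list members with any peak against RefSeq protein-coding genes matched on genomic gene length in 20 classes, and the pathway and gene family counts of the closing section.

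The alternatives were the peaks of highest fold (16984 of AAV-GFP and 20755 of AAV-NAT10), equal numbers of top peaks (16984 from each list, ranked by p-value), overlap of at least 0.5 of the peak or of both peaks, peaks merged first, at least 2 peaks per gene, the number of peaks in place of covered length, and unmatched random lists. The position of peaks in coding sequence and untranslated regions and the CXXCXXCXX motif linked to ac4C were planned and are not analysed here, since they need a genome sequence and exon annotation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.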

Results

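RIP-seq peaks were compared between the livers of mice given AAV-NAT10 and those of mice given AAV-GFP. NAT10 is the acetyltransferase that makes N4-acetylcytidine (ac4C) in RNA, and AAV is a gene delivery virus. The AAV-GFP list held 33968 peaks in 7462 genes, covering 20.4 Mb, and the AAV-NAT10 list held 41511 peaks in 8508 genes, covering 22.8 Mb. The median peak was 184 bases long (interquartile range 128 to 577) in AAV-GFP and 179 bases (124 to 491) in AAV-NAT10. The median fold enrichment was 6.33 (4.88 to 8.43) in AAV-GFP and 6.51 (4.87 to 8.90) in AAV-NAT10. Each list came from 1 IP and 1 input library of unknown depth, so all differences between the viruses lack a replicate check.

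Nat10 itself, the gene that the vector is named after, was examined first. It held 9 peaks covering 2690 bases in AAV-GFP and 10 peaks covering 2867 bases in AAV-NAT10, between positions 103721256 and 103758100 of chromosome 2 (mm10). In AAV-GFP its peak folds ranged from 3.81 to 8.20, with a median at percentile 25.3 of that list, and no peak score reached the ceiling. In AAV-NAT10 its peak folds ranged from 7.10 to 17.5, with a median of 14.9 at percentile 96.4 of that list, and 9 of the 10 peaks were at the score ceiling. The exception was the peak at the low-coordinate end of the gene (103721256 to 103721928), with a fold of 7.10 and a score of 67.1. Of the 1659 genes with at least 8 peaks in the AAV-NAT10 list, Nat10 was the only 1 with so large a share of its peaks at the ceiling. In the AAV-GFP list the peak at the same end had a fold of 5.56 and a score of 103.8, inside the range of 58.3 to 351 of the other Nat10 peaks.

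**Figure D1:**
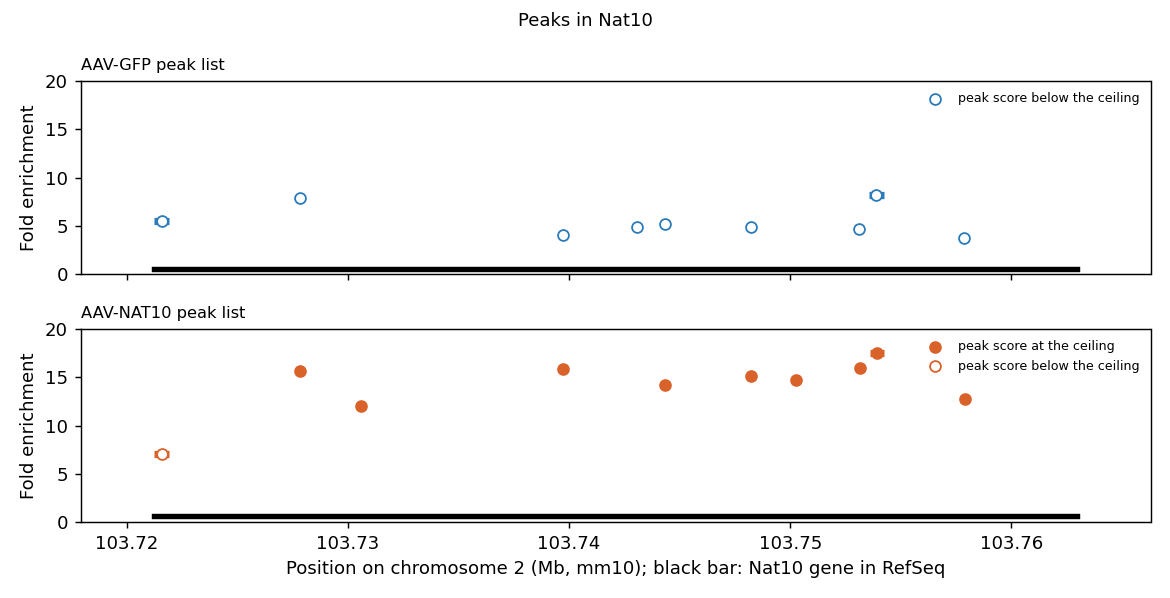
Fold enrichment (linear, IP over background) of each Nat10 peak against its position on chromosome 2 in Mb, for the AAV-GFP list (top) and the AAV-NAT10 list (bottom). Points mark peak centres, filled where the score is at the ceiling, short bars the peak extent, and the black bar the RefSeq gene; 9 of the 10 AAV-NAT10 peaks are at the ceiling, and the open point at the left end is not.

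Genes that work with NAT10 or in the same nucleolar machinery were also found. Of the 8 members of this list, which include Nat10 itself, 6 held a peak in both lists, Nat10 among them. Dkc1 held a peak only in AAV-NAT10, and Nop56 in neither. Utp20, a factor of small ribosomal subunit assembly, held 17 peaks covering 3149 bases in AAV-GFP and 24 covering 4122 bases in AAV-NAT10. Nop58 and Fbl, proteins of the box C/D small nucleolar particles, were covered over 844 and 450 bases in AAV-GFP and over 563 and 246 bases in AAV-NAT10. Thumpd1, the partner of NAT10 in tRNA acetylation, was covered over 1955 and 1976 bases. The median difference of the list, 21 bases with Nat10 (177 bases) counted, lay at percentile 25.3 of matched random lists. With equal numbers of top peaks the median was -143 bases over 4 genes (percentile 15.8), and Nop58 and Fbl had a peak only in AAV-GFP.

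The next comparison asked which peaks and genes the viruses shared. Of the AAV-GFP peaks, 29703 (87.4%, 95% interval 87.1 to 87.8) overlapped an AAV-NAT10 peak. Of the AAV-NAT10 peaks, 29682 (71.5%, 71.1 to 71.9) overlapped an AAV-GFP peak. The peaks found in only 1 list were weaker within it. AAV-NAT10 peaks with no AAV-GFP counterpart had a median fold of 4.92 against 7.35 for the overlapped ones, and AAV-GFP peaks with none had 4.88 against 6.56. Among AAV-NAT10 peaks the overlapped share was 37.6% (36.5 to 38.6) in the lowest of 5 equal score classes and 92.3% (91.7 to 92.9) in the highest, and among AAV-GFP peaks it was 71.7% (70.6 to 72.8) and 96.3% (95.8 to 96.7). Most peaks without a counterpart lay in genes that had another peak in the other list, 9660 of 11829 in AAV-NAT10 and 3818 of 4265 in AAV-GFP.

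**Figure D2:**
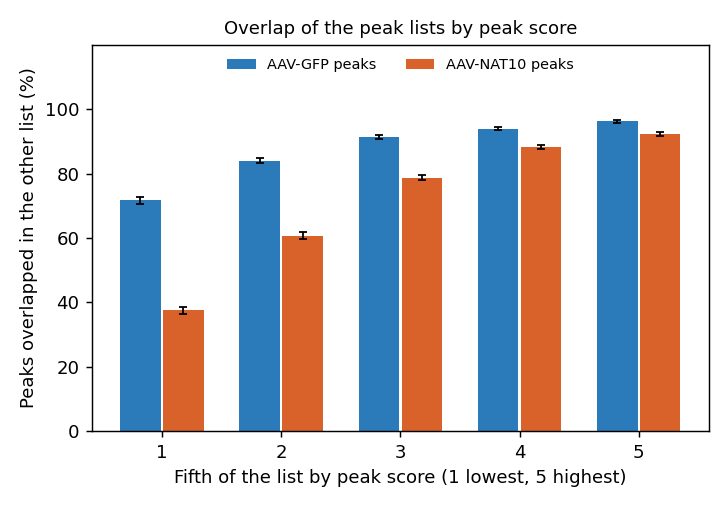
Percent of peaks overlapped by a peak of the other list, by class of each list's peak score (5 classes of equal size), for AAV-GFP peaks (blue) and AAV-NAT10 peaks (orange), with exact 95% intervals covering counting error only. The share is higher in each class than in the one before, from 71.7% to 96.3% for AAV-GFP and from 37.6% to 92.3% for AAV-NAT10.

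By gene, 7081 genes held a peak in both lists, 1427 only in AAV-NAT10 and 381 only in AAV-GFP. The shared genes made up 94.9% of the AAV-GFP genes. Genes with a peak only in AAV-NAT10 had a single peak in 967 cases (67.8%), and those only in AAV-GFP in 325 (85.3%). Among the shared genes, 4166 were covered over more bases in AAV-NAT10, 1910 over more in AAV-GFP, and 1005 equally. With 16984 top peaks taken from each list, 814 genes had a peak only in AAV-NAT10 and 622 only in AAV-GFP.

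The genes with the highest folds mostly held a peak in both lists, though their folds were not always alike. In AAV-GFP, the highest fold was 188.9, in a 45-base piece of Mup4, a major urinary protein gene whose near-identical copies make its reads uncertain. Next came Paip1 (35.8), Arid4b (32.6), Vps54 (31.5), Crebrf (29.5), Zcchc14 (29.5), Zfp236 (27.7), Tnrc18 (27.6), Pum2 (27.2) and Zc3h12c (27.1). In AAV-NAT10 the highest fold was 100.5, in a piece of only 6 bases of Nemf, followed by Slc38a2 (85.5), Zcchc14 (52.6), Serpina3i (47.1), Pum2 (39.1), Mgam (38.8), Fnip1 (36.4), Mug2 (35.9), Tulp4 (34.6) and Ptch1 (34.5). Zcchc14 and Pum2, which encodes an RNA-binding repressor of translation, were among the top 10 of both lists. The Pum2 peak lay at chromosome 12, 8749589 to 8752583, and the Slc38a2 peak, in an amino acid transporter gene, at chromosome 15, 96687392 to 96690228. All of these genes had peaks in both lists except Serpina3i, which had 1 in AAV-NAT10 alone. Most genes did so, 94.9% of those in AAV-GFP and 83.2% of those in AAV-NAT10. The highest fold of Mup4 in AAV-NAT10 was only 3.98 and that of Nemf in AAV-GFP 5.93, whereas Crebrf reached 29.5 and 30.9. Serpina3i and Mug2 belong to families of close copies, so their reads are uncertain too.

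Among genes with a peak only in AAV-NAT10, the largest covered lengths were those of Pigm (7482 bases), Plcxd2 (6375), Igf1 (6373), Slc7a2 (5971), Emc7 (5522), Abi2 (4571), Pfkfb3 (4470), Enc1 (4318), Dtx4 (4238) and Ppp1r16b (4090). A large covered length does not mark a strong signal: the highest fold was 5.69 in Pigm and 4.45 in Abi2, against 15.7 in Plcxd2. Igf1 encodes the growth factor that liver secretes in response to growth hormone. Its single AAV-NAT10 peak lay at chromosome 10, 87930675 to 87937047, with a fold of 10.1 and a score at the ceiling. Pfkfb3, which controls the glycolytic activator fructose 2,6-bisphosphate, held 7 peaks with a highest fold of 15.1. Among genes with a peak only in AAV-GFP, the largest were Gpr17 (5019 bases), Tef (3864), Zfp65 (3624), Fmo2 (3526), Nqo2 (3119), Gins2 (3015), Derl2 (2987), Filip1l (2881), Brip1os (2875) and Sfrs18 (2863). Gins2, a DNA replication factor, had the only peak at the score ceiling among these 10. Most of that peak (chromosome 8, 120578633 to 120581647) lay outside the RefSeq gene, which begins at 120581266, so its assignment to Gins2 is uncertain.

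The study concerns fatty liver disease, and the gene lists of lipid metabolism were read next. Of the 26 genes of fatty acid and triglyceride synthesis, 14 held a peak in both lists, 7 only in AAV-NAT10, none only in AAV-GFP, and 5 in neither. The 7 were Lpin1 and Lpin2, phosphatidate phosphatases of triglyceride synthesis, covered over 3057 and 3181 bases, and 5 genes that the naming rule did not select and that are named after their values were seen: Fasn, the fatty acid synthase (2253 bases), Dgat2, the enzyme of the last triglyceride step (1360), Fads1 (619), Thrsp (578) and Nr1h3, the liver X receptor alpha (305). The share of members with a peak only in AAV-NAT10, 33.3% of the 21 with any peak, lay at percentile 99.1 of matched random lists, whose median was 14.3%; this measure was chosen after the data were seen, and no other of the 19 lists lay in the highest 2.5% of random lists. With equal numbers of top peaks 7 members, Insig1 in place of Thrsp, were found only in AAV-NAT10 and none only in AAV-GFP. In the other direction, Mlxipl, the glucose-responsive factor ChREBP, was covered over 2880 bases in AAV-GFP and 1141 in AAV-NAT10, and Insig2 over 2150 and 1971. The planned measure did not set the list apart: its median difference of 213 bases lay at percentile 65.7 of random lists. By the share, related pathways of the peak lists' own annotation, also read after the data were seen, went both ways. Glycerolipid metabolism lay at percentile 99.96, non-alcoholic fatty liver disease (12 of 64 genes only in AAV-NAT10) at 44, and fatty acid metabolism (2 of 29) at 0.22.

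For cholesterol synthesis and uptake, 10 of 17 genes held peaks in both lists, 4 only in AAV-NAT10 and none only in AAV-GFP. Dhcr7, the enzyme of the last step of cholesterol synthesis, held 4 peaks covering 1712 bases in AAV-NAT10 alone, and Lss, lanosterol synthase, was covered over 4141 bases in AAV-GFP and 5610 in AAV-NAT10. Idi1 was covered over 2124 and 2088 bases. Of 22 genes of fatty acid uptake and lipid droplets, 10 were shared, 3 had a peak only in AAV-NAT10 and 1, Acsl1, only in AAV-GFP. Slc27a4, a fatty acid transporter, was covered over 605 bases in AAV-GFP and 2521 in AAV-NAT10, Plin3, a lipid droplet coat protein, over 83 and 1776, and Lipe, hormone-sensitive lipase, over 2035 and 1906. Of 23 genes of fatty acid oxidation and ketogenesis, 8 were shared, 5 had a peak only in AAV-NAT10 and 1, Hadha, only in AAV-GFP. Acot1 (1559 bases) and Cyp4a14 (1523 bases), both with close gene copies that make their reads uncertain, were found in AAV-NAT10 alone. Of the Cyp4a14 bases, 1108 lay in a piece with a fold of only 2.32. Ppargc1a, a coactivator of oxidative metabolism, was covered over 5516 bases in AAV-GFP and 4951 in AAV-NAT10. The median differences of these 3 lists, 240.5, 213 and 138.5 bases, lay at percentiles 68.5, 57.9 and 39.5.

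In lipoprotein assembly and apolipoproteins, 5 of 17 genes were shared and 2 had a peak only in AAV-NAT10, a share with any peak of 41.2% against a random median of 35.3% (percentile 73.4). Abca1, the cholesterol exporter, held 13 peaks in AAV-GFP and 24 in AAV-NAT10, over 5609 and 7195 bases, Lrp1 was covered over 3413 and 4105 bases, Abcg1 over 2061 and 1928, and Scarb1, the HDL receptor, over 754 and 621. In bile acid synthesis and transport, 7 of 18 genes were shared, 3 were found only in AAV-NAT10 and 1, Slco1b2, only in AAV-GFP. Abcg8, a subunit of the sterol exporter of bile, held 4 peaks covering 2262 bases in AAV-NAT10 alone, Abcc3 was covered over 1440 and 2161 bases, and Abcb4 over 1875 and 1861. In glucose metabolism and insulin signalling, 10 of 19 genes were shared and 5 had a peak only in AAV-NAT10, among them Igf1 and Pfkl, the liver phosphofructokinase (1433 bases). Foxo1, the insulin-regulated activator of gluconeogenic genes, was covered over 4200 bases in AAV-GFP and 3114 in AAV-NAT10. The median differences were 447, 134 and 0 bases, at percentiles 83.4, 44.3 and 7.66.

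The listed secreted plasma proteins seldom held a peak. Of 20 members 2 did (10.0%, 1.23 to 31.7), C3 and Cp, both only in AAV-NAT10, and albumin (Alb) and transferrin (Trf) did not. The pattern is that of these 20 genes. Mup4, Serpina3i and Mug2, named above for high folds, are not members. By the peak lists' own annotation, read afterwards, 27 genes of complement and coagulation cascades held a peak. C3 was among them, and the size of that pathway is not given here. Among 10000 random lists of RefSeq protein-coding genes matched on genomic length the median share was 35.0%, and the plasma proteins lay at percentile 0.46. Of 24 ribosomal protein genes 2 held a peak, Rps3 and Rpsa, at percentile 8.13. Rps3 was covered over 2372 bases in AAV-GFP and 706 in AAV-NAT10, and Rpsa over 365 and 322; pseudogene copies make both uncertain. Of 20 nuclear genes of oxidative phosphorylation 4 did, at percentile 4.86, among them Cyc1 (966 bases, only in AAV-NAT10) and Ndufs1 (507 and 1064 bases). The Cyc1 peak had a low score of 55.1. Of 18 cytochromes P450 and drug metabolism genes 7 did, at percentile 40.3: Por, the P450 reductase, was covered over 731 bases in AAV-NAT10 alone, the xenobiotic receptor Nr1i2 over 1342 and 1865, and its relative Nr1i3 over 2118 bases in AAV-GFP alone. The median differences of the oxidative phosphorylation and P450 lists, 317 and 264 bases, lay at percentiles 66.7 and 65.1, and the plasma and ribosomal protein lists had too few members with a peak for this measure. By contrast 21 of the 26 genes of fatty acid and triglyceride synthesis held a peak (80.8%, 60.6 to 93.4), at percentile 99.97, as did 14 of the 17 of cholesterol synthesis (percentile 99.94) and 15 of the 19 of glucose metabolism (percentile 99.8). These random lists include genes that liver does not express, so a high percentile is partly that of an expressed gene.

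Markers of other liver cells were unequally represented. Of 14 sinusoidal endothelial markers 13 held a peak (92.9%, 66.1 to 99.8), at percentile 99.98, and 12 of them in both lists. The scavenger receptor Stab1 was covered over 1247 bases in AAV-GFP and 1824 in AAV-NAT10, Ptprb over 11141 and 11604, Tek over 1053 and 588, and Fcgr2b over 772 and 517. Of 16 stellate cell and fibrosis markers, 6 were shared and 4 had a peak only in AAV-NAT10, namely the collagens Col1a1, Col1a2 and Col4a2 and Pdgfrb, the last over 1537 bases. Col3a1 held 1 peak of 99 bases in AAV-GFP, with a low score of 51.55, and 8 covering 1519 bases in AAV-NAT10. Reln was covered over 8617 and 7132 bases and Lrat over 5338 and 4547. With equal numbers of top peaks only 2 of these 16 markers kept any peak and none was found in 1 list alone. Of 16 macrophage and Kupffer cell markers 5 were shared and Vsig4 was found only in AAV-GFP, with a low score of 51.3. Adgre1 was covered over 450 and 1651 bases and Clec4f over 747 and 1631. Of 9 cholangiocyte markers 3 were shared and Spp1 was found only in AAV-GFP, with a low score of 66.45. Sox9 was covered over 519 and 2815 bases, Pkhd1 over 8694 and 8832, and Anxa4 over 984 and 895. The Anxa4 peaks of the 2 lists did not overlap. Of 13 lymphocyte and red cell markers 2 held a peak, Ptprc over 2949 and 2899 bases and Alas2 over 756 bases in AAV-NAT10 alone. The median differences of the endothelial, stellate, macrophage and cholangiocyte lists lay at percentiles 9.32, 61.1, 79.0 and 24.3.

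Inflammation and stress genes were read last. Of 20 acute phase and inflammation genes 8 were shared and Il1b had a peak only in AAV-NAT10. Socs3, the feedback inhibitor of cytokine signalling, was covered over 2231 and 2732 bases, Stat3 over 2618 and 3022, and Tlr4, the endotoxin receptor, over 2911 and 2694. Of 18 genes of the unfolded protein response and ER chaperones 5 were shared, 3 were found only in AAV-NAT10 and 1, Pdia6, only in AAV-GFP, with a low score of 73.5. Atf4, the transcription factor of the integrated stress response, was covered over 1276 bases in AAV-NAT10 alone, the stress sensor Ern1 over 5846 and 7012, and Sel1l over 5507 and 5479. The median differences of the 2 lists lay at percentiles 56.7 and 43.5. In all, none of the 16 gene lists with enough members had a median covered length difference beyond 95% of matched random lists.

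**Figure D3:**
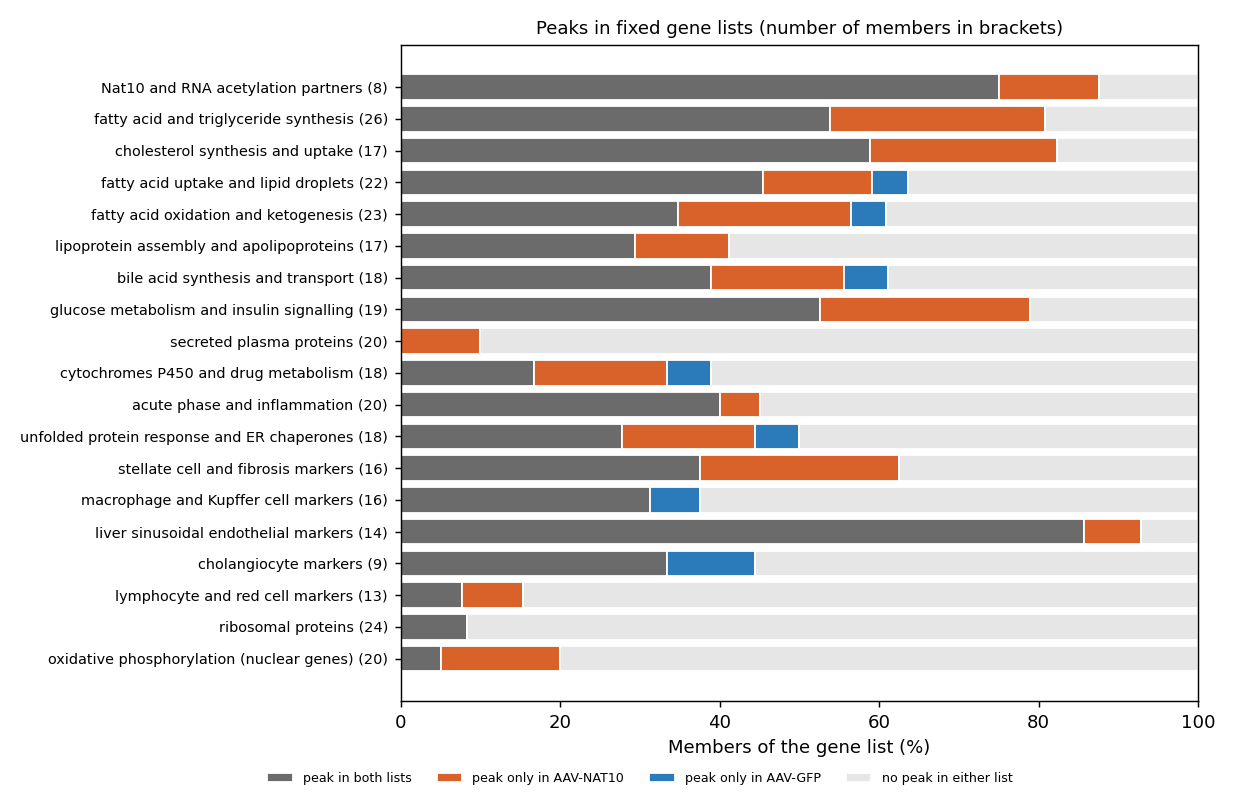
Percent of the members of each fixed gene list with a peak in both lists (dark grey), only in AAV-NAT10 (orange), only in AAV-GFP (blue) or in neither (light grey), with the number of members in brackets. Orange exceeds blue in 16 of the 19 lists, as it does over all genes (1427 against 381), while secreted plasma proteins (2 of 20 with a peak) and ribosomal proteins (2 of 24) are mostly light grey.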

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

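The overlap of the lists moved with the peaks taken, and the alternatives that took fewer changed their number and their ranking together. The share of AAV-GFP peaks overlapped was 76.5% with the peaks of highest fold alone, 74.0% with equal numbers of top peaks and 86.1% where 0.5 of both peaks had to be covered; the share of AAV-NAT10 peaks was 62.6%, 73.9% and 70.5%. Genes with a peak only in AAV-GFP numbered 622 with equal numbers of top peaks and 56 with at least 2 peaks, and those only in AAV-NAT10 numbered 814 and 460; shared genes numbered 3882 with the highest folds, 4687 with equal numbers and 4561 with at least 2 peaks in both lists. More genes were found only in AAV-NAT10 than only in AAV-GFP under each of these settings. Covering 0.5 of the peak moved neither share beyond its interval, and merging peaks first changed nothing because no peaks of a list touch. Of the gene lists, 1 lay beyond 95% of random lists with equal numbers of top peaks (fatty acid uptake and lipid droplets, 9 genes, 403 bases, percentile 97.7), and none with the other alternatives. By chance 5% of lists do so, and the cause was not tested. With the highest folds the median of that list was 0 bases (7 genes, percentile 18.2). The median for cholesterol synthesis and uptake was 996.5 bases with the highest folds (8 genes, percentile 95.1) and 0 with equal numbers (9 genes, percentile 41.2). The planned motif and transcript region results were not run. No paired analysis was possible because each group is 1 library. Without read counts, the precision of a single fold or of a missing peak is unknown.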

Other observations

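The pathway counts and the genes named from them, the comparison of plasma protein genes with lists matched on genomic length, the comparison of genes with exactly 1 peak, the shortening of the AAV-NAT10 list and the test of the end of Nat10 were chosen only after those results, or the counts behind them, had been seen. Among 200 KEGG pathways of the lists' own annotation with at least 20 genes holding a peak, 11 had a share of genes with a peak only in AAV-NAT10 in the highest 2.5% of matched random gene lists, where chance gives 5, and 6 were in the lowest 2.5%. By the covered length difference, the planned measure for gene lists, 13 pathways were in the highest 2.5% and 1 in the lowest, and none of the 11 was among these 13. The highest of the 13 were glycolysis and gluconeogenesis (percentile 99.69), endocytosis (99.63) and regulation of actin cytoskeleton (99.42). The pathways described below, apart from ribosome biogenesis, were picked by the share. In glycerolipid metabolism, 11 of 26 genes (42.3%, against a random median of 19.2%, percentile 99.96) had a peak only in AAV-NAT10 and 0 only in AAV-GFP. They include all 3 lipins (Lpin1, Lpin2 and Lpin3), Dgat2, the lipases Pnpla2 and Lipc, and the diacylglycerol kinases Dgka and Dgke; with equal numbers of top peaks the counts were 6 and 0 of 19. The biosynthesis of amino acids holds glycolytic and urea cycle enzymes such as Pklr, Pfkl, Pcx and Cps1. Of its 29 genes 17 were found only in AAV-NAT10 (58.6%, against a random median of 41.4%, percentile 99.1) and 3 only in AAV-GFP. With equal numbers of top peaks the counts were 5 and 4 of 14.

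Signalling pathways lay at both extremes. In cholinergic synapse, 9 of 43 genes were found only in AAV-NAT10 and 0 only in AAV-GFP (percentile 99.95), and 6 and 0 of 32 with equal numbers of top peaks. In alcoholism, a set with many histone genes, the counts were 20 and 1 of 55 (percentile 99.8), and 9 and 1 of 31. In gastric acid secretion they were 9 and 0 of 29, and 4 and 0 of 20, and in estrogen signalling 10 and 0 of 51, and 7 and 1 of 39. These 4 pathways share the G protein genes Gnai1 and Gnai2 among those found only in AAV-NAT10. In the lowest 2.5% lay B cell receptor signalling (1 of 51 genes only in AAV-NAT10 and 2 only in AAV-GFP), VEGF signalling (1 and 2 of 34), chemokine signalling (5 and 1 of 86, Gnai1 and Gnai2 included) and T cell receptor signalling (3 and 2 of 62). Random lists had median shares of 11.8%, 14.7%, 11.6% and 11.3% for these 4 pathways, in the same order. With equal numbers of top peaks the counts in these pathways were 3 and 4 of 42, 5 and 1 of 27, 4 and 3 of 66, and 4 and 3 of 48. VEGF signalling then had 18.5% of its genes only in AAV-NAT10, against 13.3% of all 6123 genes. These are few genes, and no percentile is given at this setting. Ribosome biogenesis was the 1 pathway in the lowest 2.5% by covered length difference (median 17 bases against 158 in random lists, percentile 2.47). By the share it lay at percentile 4, with 9 of 61 genes found only in AAV-NAT10 and 4 only in AAV-GFP; with equal numbers of top peaks the counts were 3 and 10 of 35. In fatty acid metabolism only 2 of 29 genes, Fasn and Fads1, were found only in AAV-NAT10 and 3 only in AAV-GFP. The share of 6.90% lay at percentile 0.22, with a random median of 24.1%. With equal numbers of top peaks the counts were 5 and 3 of 21. In neuroactive ligand-receptor interaction, 13 of 40 genes (32.5%, against a random median of 12.5%, percentile 99.99) were found only in AAV-NAT10 and 3 only in AAV-GFP. The 13 include the receptors Gcgr, Ghr and Lepr. With equal numbers of top peaks the counts were 4 and 4 of 25. Pathways share genes, so these counts are not independent.

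More genes had a peak only in AAV-NAT10 than only in AAV-GFP, 1427 against 381, a ratio of 3.75. The ratio was 1.31 (95% counting interval 1.18 to 1.46) with equal numbers of top peaks, 1.39 with the AAV-NAT10 list shortened to the AAV-GFP length by p-value, and 1.73 (range 1.62 to 1.83 over 100 draws) when it was thinned at random, so list length may account for part of the excess, and how much is open because ranking also changes the strength of the peaks kept. It was 2.58 with the peaks of highest fold, which kept unequal lengths, and 8.21 with at least 2 peaks per gene. Of the genes found only in AAV-NAT10, 75.5% (73.2 to 77.8) had their best peak below the median score of that list, which is consistent with peaks near the calling threshold though the interval reaches below the bound set for this test, and among genes with exactly 1 AAV-NAT10 peak the share was 79.4% (76.7 to 81.9) against 37.8% (35.4 to 40.2) of shared genes, which weak added binding would give too. Depth, IP yield and a real widening of the bound RNAs under AAV-NAT10 stay open, since each virus is 1 library and no read counts were used.

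Genes of secreted plasma proteins seldom held a peak. Short genomic length is argued against, since their share with a peak lay at percentile 0.46 of lists matched on it, while ribosomal, oxidative phosphorylation, P450 and lipoprotein genes lay within random lists. The length of their exons, to which the peaks appear cut, was not matched, so short transcripts stay open. Peaks in every gene alike, as genomic DNA in the IP alone would give, are also argued against. Of 1463 olfactory and vomeronasal receptor genes 3 held a peak (0.21%, against a random median of 8.41%, percentile 0). The receptor families hold close copies, so their reads are uncertain. The counts were 0 of 10 testis (percentile 1.515), 1 of 10 muscle (2.275) and 2 of 10 brain genes (3.82), the last within random lists. Genomic DNA present alike in IP and input would give no peak in these genes either, so it cannot be excluded here. Whether a high input level lowers the fold of such peaks stays open, because the plasma, ribosomal and oxidative phosphorylation genes together had only 5 peaks in AAV-GFP and 18 in AAV-NAT10, with a median fold at percentile 59.3 of the first list and 10.9 of the other. The design gives no biological contrast for this pattern, and none was tested.

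In AAV-NAT10, 9 of the 10 Nat10 peaks were at the score ceiling. A stronger IP of every gene is argued against, since 0.0603% of the genes with at least 8 peaks, Nat10 alone, had as large a share at the ceiling. The peak at the low-coordinate end of Nat10, which is its 3′ end by general knowledge, as the lists give no strand, had a score of 67.1 while the other 9 were at 3100. A vector transcript without the 3′ UTR could give this, but the idea came from these same peaks, so they do not test it and it stays open. The labels do not describe the insert, and vector RNA cannot be separated here from carried-over vector DNA, or bound RNA from abundant RNA.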
